A study of Homo sapiens with 12 samples.

How the data were processed

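Total RNA from 2 human melanoma cell lines, A375 and A2058, was measured on 12 Affymetrix Human Gene 1.0 ST arrays, a platform whose probe sets each summarise many short probes spread along a gene. The 4 groups were A375 with DMSO, A375 with vemurafenib, A2058 with DMSO and A2058 with vemurafenib, with 3 arrays each, taken from the sample titles. Vemurafenib is a kinase inhibitor directed at mutant BRAF, and DMSO is its solvent. Per the labels' protocols, cells received 1 µM vemurafenib for 72 h, renewed every 24 h, or an equal volume of DMSO. That text stands on all 12 samples but names A375p cells alone, so dose and time for A2058 rest on its being shared. RNA was isolated with a Qiagen column kit, amplified with the Ambion WT Expression kit and labelled with the Affymetrix WT terminal labelling kit, per the labels' protocols.

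The values analysed are the log2 expression values deposited by the authors, 1 per probe set and array, for 32321 probe sets. R 3.0.1 and the affy package are named in the submitters' processing notes; the background correction and the summary method are not given in the sources used here. That the scale is log2 was read from the deposited values, which ran from 3.24 to 13.08 and have quartiles that nearly coincide across arrays, so the authors' values were taken as already normalized between arrays and were not scaled again. An array intensity has no read depth, and the number of arrays limits the precision. Normalization of this kind removes any change shared by all genes, and signals near the lower end of the scale are compressed, so changes of dim genes are understated.

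Gene names came from the platform annotation. Exactly 1 symbol was given for 19158 probe sets, several for 1388 and none for 11775. Symbols were updated through the Entrez number with the RefSeq gene table of assembly GRCh38.p14, which matched 19128 of the probe sets with 1 symbol and was used for names alone. Probe sets with several symbols or none were left out of the gene table because no single gene can be named for them. For the 637 genes with several probe sets, the one with the highest mean over the 12 arrays was kept, which left 18404 genes. No coordinates are given, since no genome build is named for these values. No array was an exact copy of another.

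All 12 arrays entered 1 linear model with 4 group means in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes; 8 residual and 3.98 prior degrees of freedom). The contrasts were vemurafenib minus DMSO in A375, the same in A2058, the difference of these responses (A375 minus A2058), and A375 DMSO minus A2058 DMSO. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05; genes also changed at least 2-fold were counted separately. Standard errors are those of the moderated fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists per contrast. Of these, 20 describe pathways and cell states and 4 hold markers of fibroblasts, blood and immune cells, epithelial cells and endothelial cells. They were written from general knowledge; 688 of their 748 entries were measured, and some genes stand in more than 1 list. Camera asks whether a list moved relative to all other genes. The same test with a correlation estimated per list, and fry, which asks whether a list's own genes move, were run beside it.

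The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each vemurafenib comparison the rule names the 5 largest rises and the 5 largest falls among called genes whose 3 treated arrays all lie on the same side of the 3 DMSO arrays, and DUSP6, SPRY4, ETV5, CCND1, MKI67, MITF, ERBB3 and EGFR whatever their result. It also names up to 2 called members with the largest change for each list past its test. It adds the 5 largest differences of each sign for the response and the 6 genes highest in each line for the DMSO comparison. Exceptions are the members of a list that moved against it, or that were not called, where they number 5 or fewer, as well as the genes of the closing part; these were chosen after their values were seen. A list of hypoxia inducible genes and a list of interferon ligand genes were written after the first fit.

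The steps were tested on simulated data with the real means and spreads of the 18404 genes. With 50 genes changed at each size, the A375 contrast recovered 38%, 76%, 100% and 100% at log2 changes of 0.25, 0.5, 1 and 2, with 6 false calls (3.68% of calls). For A2058 these shares were 40%, 82%, 100% and 100%, with 5 false calls (3.01%). Among 500 random lists, 7 in the A375 contrast and 4 in the A2058 contrast had a camera p under 0.05, and all 20 lists shifted by 0.3 were called in each. The simulated noise was independent between genes, so these lists held no correlation. Their rate of false calls does not carry over to the real lists, where the estimated correlation reached 0.483 for G2/M genes. Far fewer genes were changed in the simulation than were called in the real data, 37% in A375 and 27.1% in A2058. The Benjamini-Hochberg cut-off and camera's background of other genes therefore differed. Thus the recovered shares of genes and lists do not carry over either.

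Alternatives were quantile normalization, shifting each array to the same median, leaving out the 30% of genes with the lowest mean, all probe sets, averaged probe sets, a trended and robust prior, array weights, a replicate block, the 6 arrays of a comparison alone, and leaving out each array in turn. Leaving out A375 vemurafenib replicate 1 and A2058 DMSO replicate 2 together was added after seeing the data. Triplicates were handled in parallel per the series' design text, but nothing says that they came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical. Any batch that coincides with the cell line cannot be told apart from the line; it drops out of the vemurafenib contrasts as far as it is additive. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.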

Results

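The series asked how gene expression in A375 and A2058, established human melanoma cell lines, responds to vemurafenib. The data are 12 arrays, 3 for each of 4 groups, with 18404 named genes. Replicates within a group correlated at r = 0.9978 to 0.9989 across these genes, except in A375 vemurafenib. There replicate 1 correlated at 0.9939 and 0.9941 with the other arrays of its group, which reached 0.9982 with each other. The median SD of a gene within a group was 0.0461 in A375 DMSO, 0.0866 in A375 vemurafenib, 0.0591 in A2058 DMSO and 0.0507 in A2058 vemurafenib. Changes below are log2 differences of group means ± SE from the limma fit, with 3 arrays per group. For each gene named as rising or falling in the comparisons below, all 3 vemurafenib arrays lay on that side of the 3 DMSO arrays. Genes named because they moved against their list, or were not called in it, were chosen after their values were seen.

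The first question was what vemurafenib changed in A375. The largest rises were those of IFIT1, an interferon stimulated gene whose product binds viral RNA (6.0 ± 0.057, 64.1-fold), and the complement protease C1S (5.29 ± 0.052). XAF1, an interferon induced regulator of apoptosis (5.19 ± 0.040), the vitamin B12 binding protein TCN1 (5.0 ± 0.051) and OAS2, a sensor of double-stranded RNA (4.99 ± 0.048), followed. The largest falls were those of SYTL5, a Rab effector of vesicle traffic (-5.24 ± 0.067), LOXL4, a lysyl oxidase of the matrix (-4.67 ± 0.052), the matrix glycoprotein TINAGL1 (-4.47 ± 0.073), CEMIP, which takes part in hyaluronan breakdown (-4.32 ± 0.046), and the integrin activator FERMT1 (-4.14 ± 0.048). Adjusted p for these 10 genes lay between 5.88e-16 and 1.71e-13. Among the genes fixed beforehand, the ERK phosphatase DUSP6 (-1.69 ± 0.055), the ERK pathway inhibitor SPRY4 (-3.91 ± 0.060), the transcription factor ETV5 (-1.33 ± 0.058) and cyclin D1, CCND1 (-1.93 ± 0.057), fell. MKI67, a marker of cycling cells, rose by 0.36 ± 0.059 (adjusted p = 0.00028) and MITF, the melanocyte master regulator, by 0.73 ± 0.047 (adjusted p = 5.66e-08). The receptor ERBB3 fell by a small amount (-0.14 ± 0.035, adjusted p = 0.00733), and EGFR was not called (-0.19 ± 0.10, adjusted p = 0.208).

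Of 38 measured interferon stimulated genes in A375, 36 rose and none fell, the same counts as when adjusted over the list alone. The median was 3.08 (camera adjusted p = 4.06e-37, and adjusted p = 0.0084 with an estimated correlation). The 2 members not called were ISG20 (0.095 ± 0.085) and GBP2 (-0.17 ± 0.095). Of 23 listed antigen processing and presentation genes 15 were measured, and all 15 rose, also when adjusted over the list alone. The median was 1.02 (adjusted p = 5.41e-14, and adjusted p = 0.00345 with an estimated correlation). The peptide transporter TAP1 (1.58 ± 0.043) and the immunoproteasome subunit PSMB9 (1.45 ± 0.048) rose most; probes of HLA genes in this list can be shared within the family. Mitotic and G2/M genes rose by less: 37 of 45 were called up and none down (39 up adjusted over the list alone), with KIF20A, a kinesin of cytokinesis, at 0.95 ± 0.056, and the spindle protein DLGAP5 at 0.75 ± 0.076. The G2/M median was 0.39 (adjusted p = 2.04e-12), and this call was lost at adjusted p = 0.259 with an estimated correlation. Lysosomal and autophagy genes had 23 rises and 9 falls among 45 (24 and 9 adjusted over the list alone) and a median of 0.15 (adjusted p = 0.00513, but adjusted p = 0.259 with an estimated correlation). Cathepsin K, CTSK, rose by 3.18 ± 0.092, while BNIP3, a mitophagy receptor that is also induced by hypoxia, fell (-1.78 ± 0.074). A375 vemurafenib replicate 1 stood apart from its group; without it the counts of rises were 36 interferon, 15 antigen presentation, 40 G2/M and 26 lysosomal genes.

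Transcriptional targets and feedback regulators of ERK fell in A375: 26 of 28 were called down, also adjusted over the list alone. The median was -0.97 (camera adjusted p = 4.4e-19, and adjusted p = 0.000388 with an estimated correlation). Beside SPRY4, the transcription factor ETV4 fell most (-3.25 ± 0.075). The inhibitor SPRED1 rose (0.18 ± 0.042), and the AP-1 subunit FOSL1 was not called (-0.26 ± 0.14) but passed without A2058 vemurafenib replicate 1 (adjusted p = 0.0137, against 0.0137 to 0.334 over all left-out arrays). Of 21 genes of glucose uptake and glycolysis, 20 fell, also adjusted over the list alone. The median was -0.71 (adjusted p = 1.47e-14, and adjusted p = 0.00194 with an estimated correlation). PDK1, an inhibitory kinase of pyruvate dehydrogenase (-2.78 ± 0.049), and aldolase C, ALDOC (-2.68 ± 0.069), led the falls, and PFKFB2, which makes an activator of glycolysis, rose (0.65 ± 0.096). DNA replication and G1/S genes fell in 29 of 40 cases (30 adjusted over the list alone). The median was -0.42 (adjusted p = 6.06e-08, but adjusted p = 0.246 with an estimated correlation). The exonuclease EXO1 (-0.72 ± 0.056) and the licensing factor CDT1 (-0.72 ± 0.058) fell most, and PCNA (0.26 ± 0.051), GINS3 (0.28 ± 0.072) and FEN1 (0.15 ± 0.051), also replication genes, rose. The FEN1 call (adjusted p = 0.0425) was lost at adjusted p of 0.0515 to 0.163 without A375 DMSO replicate 1 or 3, A375 vemurafenib replicate 2 or 3, A2058 DMSO replicate 2 or any A2058 vemurafenib array. Nucleolar ribosome biogenesis genes had 18 falls and 6 rises among 41 (19 and 6 adjusted over the list alone) and a median of -0.13 (adjusted p = 0.00774, but adjusted p = 0.445 with an estimated correlation). The ribosome assembly factor NOB1 (-1.17 ± 0.044) and the nucleolar chaperone NPM3 (-0.65 ± 0.073) fell most in this list, whose call was lost without A375 vemurafenib replicate 1 (adjusted p = 0.117) and with array weights (0.066). Without that array, which stood apart from its group, 25 ERK, 20 glycolysis, 27 G1/S and 18 ribosome biogenesis genes were called down.

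The other 16 lists did not pass the test in A375. Medians were -0.20 for AP-1 and immediate early genes (adjusted p = 0.062), 0.22 for p53 targets (0.0672), -0.12 for receptor tyrosine kinases and ligands (0.0873) and -0.19 for cholesterol synthesis (0.133). They were 0.046 for pigment cell differentiation (adjusted p = 0.133), 0.045 for the undifferentiated, invasive melanoma state (0.47), -0.090 for NF-kB associated cytokines and chemokines (0.274) and -0.00039 for ATF4 and ER stress targets (0.147). For BCL2 family genes the median was 0.011 (adjusted p = 0.685), for FOXO targets 0.0058 (0.685), for matrix and adhesion genes 0.020 (0.685) and for oxidative phosphorylation -0.0091 (0.87). A median near 0 can hide changes in both directions. Called up and down were 14 and 12 of 36 undifferentiated state genes, 10 and 13 of 27 cytokines and 19 and 16 of 45 matrix genes. For oxidative phosphorylation these were 8 and 7 of 48, and 37% of all genes were called in A375. Markers of other cell types had medians of 0.031 for fibroblasts (adjusted p = 0.0571; mean 0.31, 5 of 12 called up and none down, with LUM at 2.15 ± 0.11), 0.028 for blood and immune cells (0.685), -0.10 for epithelial cells (0.126) and -0.022 for endothelial cells (0.685). For oxidative phosphorylation the mean (0.0011) had the opposite sign to the median and the test, as had the immune marker mean (-0.00092). The p53 list passed without A375 vemurafenib replicate 1 (adjusted p = 0.0305), the AP-1 list without that array (0.0387) or A375 DMSO replicate 3 (0.0473), and the fibroblast markers without A375 DMSO replicate 2 (0.0325) or A375 vemurafenib replicate 2 (0.0431) or 3 (0.0312).

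In all, 6816 of 18404 genes were called in A375 by limma, 3265 up and 3551 down, and 773 of them changed at least 2-fold (356 up, 417 down). The median SE of a change was 0.0583. The fit gave each gene 1 spread shared by all 4 groups, so the SE was the same in both lines. Yet the median SD of a gene was highest in A375 vemurafenib (0.0866). From the 6 A375 arrays alone, 6020 genes were called. Without A375 vemurafenib replicate 1, 7785 genes were called.

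**Figure D1:**
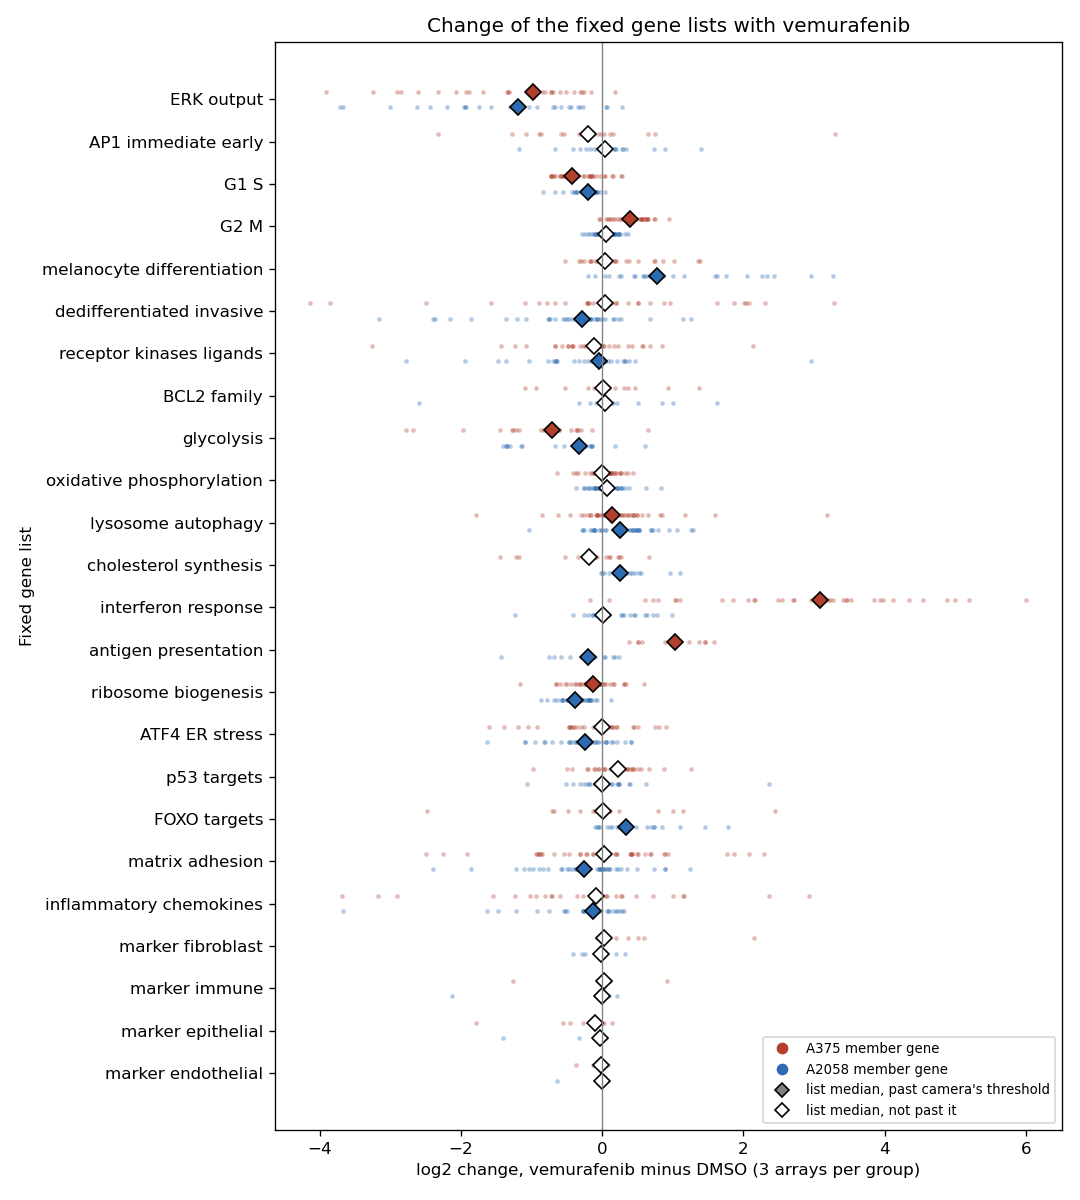
Log2 change with vemurafenib (horizontal axis) of the member genes of each fixed list (dots) and the list median (diamonds, filled where camera passed its threshold and open where it did not), for A375 and A2058. The interferon list has a median of 3.08 in A375 and 0.013 in A2058, and the pigment cell list 0.046 in A375 and 0.77 in A2058.

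The same question was put to A2058. The largest rises were those of TYRP1, an enzyme of melanin synthesis (3.26 ± 0.13, 9.59-fold), the small heat shock protein CRYAB (3.21 ± 0.14), the ATP-gated channel P2RX7 (3.17 ± 0.097), the potassium channel KCNJ13 (3.01 ± 0.073) and the receptor kinase KIT (2.96 ± 0.047). The largest falls were those of MRGPRX4, a receptor whose probes can be shared with near-identical family members (-4.15 ± 0.079), RGS5, a regulator of G protein signalling (-3.85 ± 0.093), ETV4 (-3.71 ± 0.075), the neutrophil chemokine CXCL8 (-3.67 ± 0.074) and OTULINL (-3.65 ± 0.061). Adjusted p for these 10 genes lay between 1.12e-12 and 2.53e-09. DUSP6 (-2.63 ± 0.055), SPRY4 (-3.0 ± 0.060), ETV5 (-1.95 ± 0.058) and CCND1 (-2.43 ± 0.057) fell and MITF rose (0.73 ± 0.047, adjusted p = 1.21e-07). MKI67 (-0.028 ± 0.059, adjusted p = 0.839), ERBB3 (-0.040 ± 0.035, adjusted p = 0.522) and EGFR (-0.16 ± 0.10, adjusted p = 0.359) were not called, but EGFR passed without A2058 DMSO replicate 3 (-0.30, adjusted p = 0.013, against 0.013 to 0.771 over all left-out arrays).

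Of 33 pigment cell differentiation genes and MITF targets, 29 rose in A2058 and none fell (30 rose adjusted over the list alone). The median was 0.77 (camera adjusted p = 3.41e-23, and adjusted p = 5.46e-05 with an estimated correlation). GPR143 (-0.10 ± 0.072), ST3GAL6 (-0.20 ± 0.10), BIRC7 (0.039 ± 0.082) and S100B (0.090 ± 0.040) were not called. Lysosomal and autophagy genes rose in 30 of 45 cases and fell in 6 (30 and 8 adjusted over the list alone), with CTSK at 1.28 ± 0.092 and the sphingomyelinase SMPD1 at 1.25 ± 0.054. The median was 0.26 (adjusted p = 3.21e-08, and adjusted p = 0.0233 with an estimated correlation). Of 19 cholesterol genes, 14 rose, also adjusted over the list alone. The median was 0.26 (adjusted p = 5.32e-07, and adjusted p = 0.0164 with an estimated correlation). The synthesis enzymes HMGCS1 (1.11 ± 0.062) and LSS (0.96 ± 0.046) rose most, and FDPS (0.10 ± 0.055), ACAT2 (0.22 ± 0.10), PMVK (-0.0015 ± 0.062), STARD4 (0.026 ± 0.066) and TM7SF2 (-0.013 ± 0.096) were not called, although ACAT2 passed without A375 vemurafenib replicate 1 (adjusted p = 0.00422, against 0.00422 to 0.342). FOXO targets had 14 rises and no fall among 22 (15 rises adjusted over the list alone), with KLHL24 at 1.79 ± 0.086 and the stress protein SESN3 at 1.46 ± 0.050. The median was 0.34 (adjusted p = 5.25e-08, and adjusted p = 0.0164 with an estimated correlation).

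ERK targets fell in A2058 in 25 of 28 cases, also adjusted over the list alone. The median was -1.20 (camera adjusted p = 2.86e-26, and adjusted p = 5.46e-05 with an estimated correlation). ETV4 and CXCL8, given above, fell most, TRIB2, a pseudokinase, rose (0.27 ± 0.065), and EGR1 (0.063 ± 0.065) and VGF (0.055 ± 0.098) were not called. Ribosome biogenesis genes fell in 35 of 41 cases and none rose (38 fell adjusted over the list alone), led by the ribosome assembly factor MRTO4 (-0.86 ± 0.056) and the RNA polymerase I subunit POLR1B (-0.79 ± 0.050). The median was -0.38 (adjusted p = 1.52e-18, and adjusted p = 0.022 with an estimated correlation). Glycolysis genes fell in 18 of 21 cases (19 adjusted over the list alone), with PDK1 at -1.41 ± 0.049 and PFKFB3, which makes an activator of glycolysis, at -1.36 ± 0.064. The median was -0.33 (adjusted p = 2.15e-13, and adjusted p = 0.0018 with an estimated correlation). PFKFB2 (0.61 ± 0.096) and the phosphofructokinase PFKM (0.19 ± 0.048) rose, and ALDOC (-0.18 ± 0.069) was not called. The PFKM call was lost without A2058 DMSO replicate 1 (adjusted p = 0.0533) or A2058 vemurafenib replicate 1 (0.0537), and ALDOC passed without A2058 vemurafenib replicate 2 (0.0273, against 0.0273 to 0.335). G1/S genes fell in 22 of 40 cases and none rose (26 fell adjusted over the list alone), with the replication licensing factor CDC6 at -0.83 ± 0.13 and the ribonucleotide reductase subunit RRM2 at -0.67 ± 0.083. The G1/S median was -0.20 (adjusted p = 1.81e-09, but adjusted p = 0.0816 with an estimated correlation).

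Genes of the undifferentiated, invasive melanoma state fell in 20 of 36 cases and rose in 5 (21 and 7 adjusted over the list alone). The median was -0.28 (camera adjusted p = 2.87e-08, and adjusted p = 0.00201 with an estimated correlation). The ectonucleotidase NT5E (-3.16 ± 0.050) and the collagenase MMP1 (-2.39 ± 0.080) fell most, while the transcription factors SNAI2 (1.26 ± 0.045), ZEB2 (1.15 ± 0.041) and FOXF2 (0.68 ± 0.070), the matrix protease MMP14 (0.27 ± 0.068) and fibronectin, FN1 (0.23 ± 0.044), rose; the ZEB2 change was 0.68 when its probe sets were averaged. Matrix and adhesion genes had 23 falls and 8 rises among 45 (23 and 9 adjusted over the list alone), with integrin alpha 3, ITGA3, at -1.85 ± 0.051. The median was -0.25 (adjusted p = 1.98e-05, and adjusted p = 0.0233 with an estimated correlation). Cytokines and chemokines had 13 falls among 27 (also adjusted over the list alone), with the prostaglandin synthase PTGS2 at -1.64 ± 0.044. The median was -0.14 (adjusted p = 0.000326, and adjusted p = 0.0164 with an estimated correlation; median -0.21 without A2058 DMSO replicate 3). Against this direction IL24 (0.22 ± 0.051), the NF-kB regulators NFKBIA (0.28 ± 0.049) and NFKBIZ (0.25 ± 0.066) and the superoxide dismutase SOD2 (0.31 ± 0.067) rose. Adjusted over the list alone, 6 genes rose in all. The NFKBIZ call was lost without A2058 DMSO replicate 1 (adjusted p = 0.0662) or A2058 vemurafenib replicate 3 (0.0566). ATF4 and ER stress targets had 19 falls among 34 (20 adjusted over the list alone), led by the cystine transporter SLC7A11 (-1.62 ± 0.054) and the arginine transporter SLC7A1 (-1.09 ± 0.057). The median was -0.24 (adjusted p = 5.5e-07, and adjusted p = 0.0232 with an estimated correlation). The amino acid transporter SLC7A5 (0.41 ± 0.045), the stress protein NUPR1 (0.40 ± 0.058) and HERPUD1 (0.32 ± 0.057) rose.

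Receptor tyrosine kinases and ligands had 15 falls and 6 rises among 38 in A2058 (15 and 7 adjusted over the list alone), with the EGFR ligand TGFA at -2.78 ± 0.11 opposite to KIT. Their median was -0.045 (camera adjusted p = 0.00128, and adjusted p = 0.0164 with an estimated correlation), and -0.073, -0.075 and -0.073 without A2058 DMSO replicate 1, A2058 DMSO replicate 3 and A2058 vemurafenib replicate 3. Of 15 measured antigen presentation genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone). The median was -0.20 (adjusted p = 0.00196, but adjusted p = 0.0787 with an estimated correlation). HLA-DMB (-1.44 ± 0.056) and HLA-DMA (-0.75 ± 0.040), which load peptides on MHC class II and whose probes can be shared within the HLA family, fell most. Beta-2 microglobulin, B2M (0.23 ± 0.043), the MHC class I regulator NLRC5 (0.17 ± 0.055) and TAP1 (0.15 ± 0.043) rose, and TAPBP (0.040 ± 0.040), PSMB8 (-0.29 ± 0.11), PSMB10 (0.026 ± 0.065) and ERAP2 (-0.10 ± 0.11) were not called. The NLRC5 call was lost at adjusted p of 0.0833 to 0.127 without A2058 DMSO replicate 1 or 3 or A2058 vemurafenib replicate 2 or 3, and the TAP1 call at 0.0533 to 0.0711 without A2058 DMSO replicate 1 or 3 or A2058 vemurafenib replicate 1 or 2. PSMB8 passed without A375 vemurafenib replicate 1 (adjusted p = 0.00212, against 0.00212 to 0.258).

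The other 10 lists did not pass the test in A2058. Medians were 0.013 for interferon stimulated genes (adjusted p = 0.189), 0.048 for G2/M genes (0.239), 0.037 for AP-1 and immediate early genes (0.524) and 0.062 for oxidative phosphorylation (0.294). They were 0.034 for BCL2 family genes (adjusted p = 0.294), -0.0050 for p53 targets (0.991), -0.014 for fibroblast markers (0.521), 0.0043 for blood and immune markers (0.835), -0.024 for epithelial markers (0.239) and 0.0033 for endothelial markers (0.654). Of 38 interferon stimulated genes, 11 were called up and 3 down in A2058, with changes from -1.23 to 0.99. Fry's directional test called this list up (adjusted p = 0.0214). Of all genes, 27.1% were called in A2058. The mean of the p53 list (0.053) had the opposite sign to its median and test, and the means of the immune (-0.12) and endothelial (-0.055) markers and their tests had the opposite sign to their medians. The G2/M list passed with quantile normalization (adjusted p = 0.0381). In all, 4991 of 18404 genes were called in A2058 by limma, 2691 up and 2300 down, and 365 changed at least 2-fold (154 up, 211 down), with a median SE of 0.0583. From the 6 A2058 arrays alone, 5453 genes were called. The gap in counts between the lines thus depends on the spread shared by all groups.

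Vemurafenib moved many genes the same way in both lines. Of the called genes, 1200 rose in both and 1260 fell in both, where independent lists of these sizes would share 477 and 444. Opposite calls were made for 332 genes up in A375 and down in A2058 (408 for independent lists) and 480 genes the other way (519). Both contrasts use the same spread of each gene, so their calls can overlap beyond these numbers without a shared response. Such overlap would raise opposite calls as well, and these were below the numbers for independent lists. At 2-fold or more, 43 genes rose and 112 fell in both lines, against 2.98 and 4.78. Across the 18404 genes the responses correlated at Pearson's r = 0.369 and Spearman's rho = 0.294; genes are not independent replicates, and the lines have separate DMSO arrays. The spread of Pearson's r over pairs of 1 vemurafenib array from each line was 0.012 (SD).

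**Figure D2:**
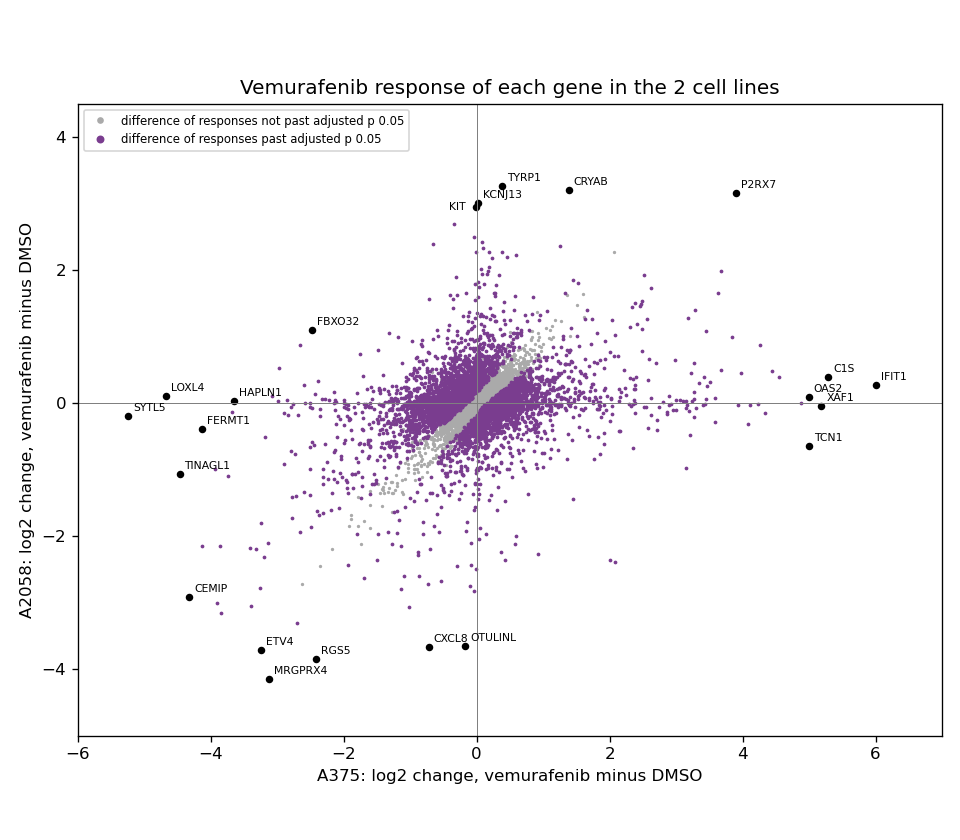
Log2 change with vemurafenib in A375 (horizontal axis) against that in A2058 (vertical axis), 1 point per gene, purple where the difference of the responses passed the test and grey elsewhere, with the genes of largest change labelled. Pearson's r is 0.369, and IFIT1 lies at 6.0 in A375 and 0.28 in A2058.

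The difference between the lines was tested as a contrast of its own, the response of A375 minus that of A2058. It was largest for IFIT1 (5.72 ± 0.081), TCN1 (5.64 ± 0.073), XAF1 (5.22 ± 0.057), OAS2 (4.91 ± 0.067) and C1S (4.90 ± 0.073). The most negative differences were those of SYTL5 (-5.04 ± 0.094), LOXL4 (-4.77 ± 0.074), FERMT1 (-3.75 ± 0.069), HAPLN1, a link protein of the hyaluronan matrix (-3.68 ± 0.096), and FBXO32, a ubiquitin ligase subunit and FOXO target (-3.58 ± 0.12). Adjusted p for these 10 genes lay between 3.41e-14 and 2.81e-10. HAPLN1 fell in A375 (-3.65 ± 0.068) and was not called in A2058 (0.027 ± 0.068), and FBXO32 fell in A375 (-2.47 ± 0.084) and rose in A2058 (1.10 ± 0.084). HAPLN1 and LOXL4 were already lower in A2058 than in A375 in DMSO, by 6.01 to 6.06 and 5.78 to 5.87 over all settings. A2058 may thus have had little room for a fall, and their differences need not mean that the lines respond differently to the drug.

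Among the lists, the response of 36 of 38 interferon stimulated genes was higher in A375, also adjusted over the list alone, with a median difference of 2.99 (camera adjusted p = 7.72e-44, and adjusted p = 0.00662 with an estimated correlation); ISG20 (0.13 ± 0.12) and MX2 (0.079 ± 0.063) were not called. All 15 measured antigen presentation genes were higher, also adjusted over the list alone, by a median of 1.18 (camera adjusted p = 1.2e-17, and adjusted p = 0.00214 with an estimated correlation). HLA probes can be shared within the family. For G2/M genes 29 of 45 were higher and none lower (30 higher adjusted over the list alone), by a median of 0.41 (adjusted p = 1.29e-09, but adjusted p = 0.288 with an estimated correlation). Pigment cell genes had a lower response in A375 in 24 of 33 cases, also adjusted over the list alone. The median was -0.68 (adjusted p = 1.29e-09, and adjusted p = 0.00202 with an estimated correlation). Higher in A375 were the melanosome protein GPNMB (0.61 ± 0.073), S100B (0.92 ± 0.056) and the transcription factor TFAP2A (0.55 ± 0.18), whose call (adjusted p = 0.0326) was lost at adjusted p of 0.0602 to 0.086 without A375 DMSO replicate 1 or 2, A375 vemurafenib replicate 2 or 3, A2058 DMSO replicate 1 or 3, or A2058 vemurafenib replicate 1 or 3. Cholesterol genes were lower in 13 of 19 cases and higher in none (15 lower adjusted over the list alone). The median was -0.44 (adjusted p = 2.16e-07, and adjusted p = 0.0134 with an estimated correlation). Genes of the undifferentiated state were higher in 19 of 36 cases and lower in 8 (20 and 9 adjusted over the list alone). The median was 0.28 (adjusted p = 0.000127, and adjusted p = 0.0134 with an estimated correlation). A375 vemurafenib replicate 1 stood apart from its group; without it 36 interferon, 15 antigen presentation and 37 G2/M genes were called higher and 24 pigment cell and 15 cholesterol genes lower.

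A further 6 lists passed the difference test, but not with an estimated correlation. Glycolysis genes were lower in 10 of 21 cases, also adjusted over the list alone, by a median of -0.15 (adjusted p = 0.000675, but adjusted p = 0.0604 with an estimated correlation), and the glucose transporter SLC2A1 was higher (0.27 ± 0.059). Ribosome biogenesis genes were higher in 18 of 41 cases (20 adjusted over the list alone, and 28 with A375 vemurafenib replicate 1 and A2058 DMSO replicate 2 left out), by a median of 0.19 (adjusted p = 0.00011, but adjusted p = 0.288 with an estimated correlation). NOB1 (-0.70 ± 0.062) and fibrillarin, FBL (-0.27 ± 0.083), were lower; the FBL call (adjusted p = 0.0264) was lost at adjusted p of 0.05 to 0.0707 without A375 DMSO replicate 1 or 3, A2058 DMSO replicate 2 or 3, or A2058 vemurafenib replicate 1 or 2. ATF4 and ER stress targets were higher in 16 of 34 cases (17 adjusted over the list alone), by a median of 0.20 (adjusted p = 0.0071, but adjusted p = 0.242 with an estimated correlation), and VLDLR (-1.60 ± 0.073), SLC7A5 (-1.33 ± 0.064), CTH (-0.63 ± 0.11), EIF4EBP1 (-0.44 ± 0.086) and DDIT4 (-0.33 ± 0.067) were lower. FOXO targets were lower in 11 of 22 cases (12 adjusted over the list alone), by a median of -0.23 (adjusted p = 0.0097, but adjusted p = 0.242 with an estimated correlation), and SESN3 (0.99 ± 0.071), SOD2 (0.70 ± 0.095) and TXNIP (0.45 ± 0.058) were higher. AP-1 and immediate early genes were lower in 10 of 21 cases (14 adjusted over the list alone), by a median of -0.26 (adjusted p = 0.0158, but adjusted p = 0.376 with an estimated correlation), and JUN (1.89 ± 0.097), FOSL1 (0.91 ± 0.19), ATF3 (0.83 ± 0.087) and KLF4 (0.39 ± 0.078) were higher. Fibroblast markers had a median difference of 0.12 over 12 genes (adjusted p = 0.0288, but adjusted p = 0.231 with an estimated correlation), with the matrix proteoglycans LUM (2.56 ± 0.15) and DCN (0.26 ± 0.053), the actin ACTA2 (0.84 ± 0.065) and the receptor PDGFRB (0.40 ± 0.077) higher, also adjusted over the list alone. The fibroblast call was lost with array weights (adjusted p = 0.0776) and without A375 vemurafenib replicate 1, which stood apart from its group (median 0.080, adjusted p = 0.102); the median was 0.081 without A2058 DMSO replicate 1.

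The remaining 12 lists did not pass the difference test. Medians were 0.28 for ERK targets (adjusted p = 0.159), -0.087 for G1/S genes (0.103), -0.090 for lysosomal genes (0.0662), 0.088 for p53 targets (0.116), 0.061 for matrix and adhesion genes (0.103) and 0.038 for cytokines and chemokines (0.116). They were -0.027 for receptor kinases (adjusted p = 0.494), -0.024 for BCL2 family genes (0.958), -0.047 for oxidative phosphorylation (0.246), 0.024 for immune markers (0.236), -0.10 for epithelial markers (0.438) and -0.018 for endothelial markers (0.958). Single members could still differ in both directions. Of 28 ERK targets 15 were called higher and 10 lower in A375, and of 45 matrix genes 19 and 14. Of 16 BCL2 family genes these were 3 and 2, and 29.5% of all genes were called. Signs disagreed in 4 of these lists. The ERK mean was -0.014, although its median and test were positive, the receptor kinase mean was 0.060 and its test positive, although its median was negative, and the BCL2 and endothelial lists had negative medians and means (-0.031 and -0.0032) but a positive test. The G1/S list passed without A375 vemurafenib replicate 2 (adjusted p = 0.0457) or 3 (0.0332), and the lysosomal list without A375 vemurafenib replicate 2 (0.0457) or 3 (0.0379) or A2058 DMSO replicate 3 (0.046). In all, 5434 genes differed in response by limma, 2416 higher and 3018 lower in A375, 772 of them by at least 2-fold (380 and 392), with a median SE of 0.0825.

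**Figure D3:**
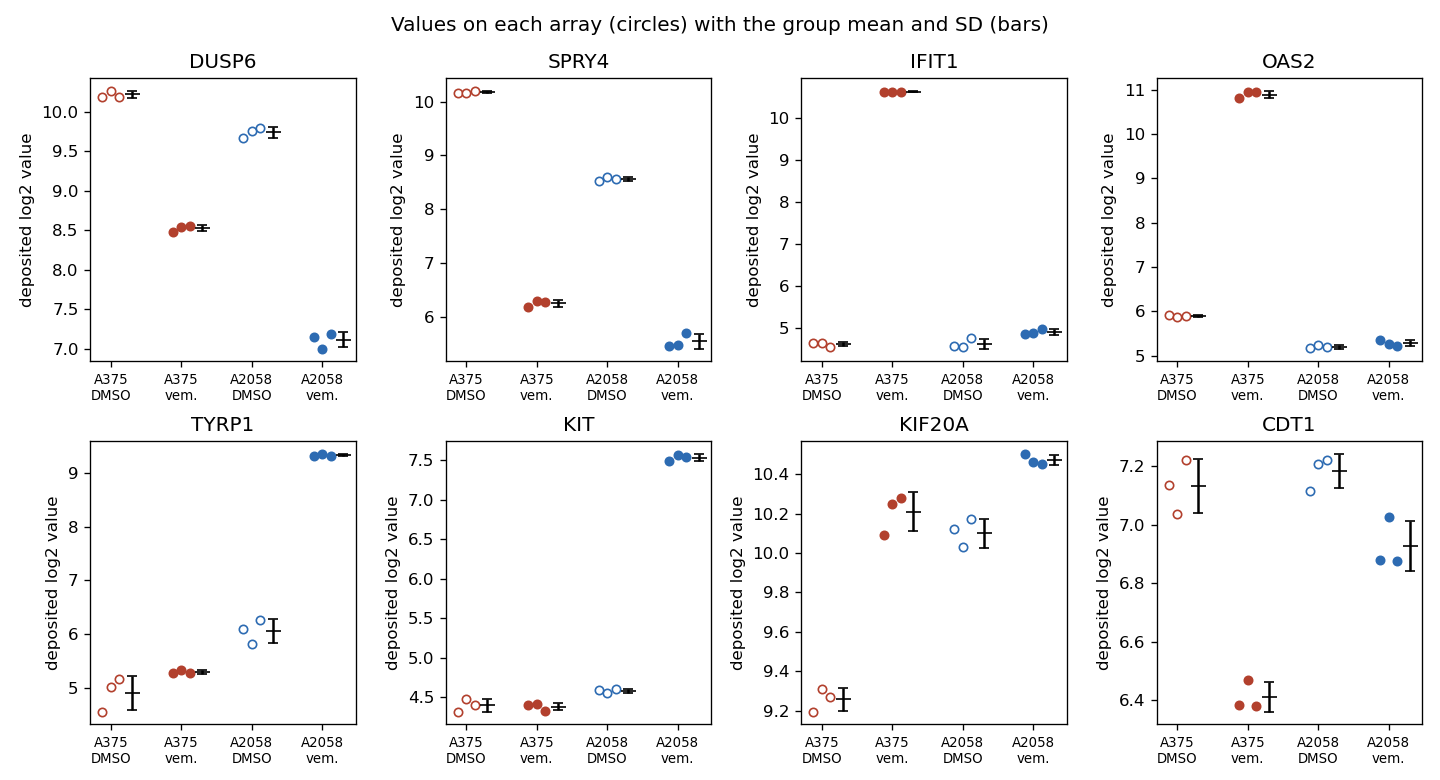
Log2 expression (vertical axis, not starting at 0) of DUSP6, SPRY4, IFIT1, OAS2, TYRP1, KIT, KIF20A and CDT1 on each of the 12 arrays (points) with the mean and SD of the 3 arrays per group (bars). IFIT1 averages 4.62 in A375 DMSO and 10.62 in A375 vemurafenib, against 4.63 and 4.91 in A2058.

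The lines also differed without the drug. In DMSO, A375 had higher levels of complement component C3 (6.55 ± 0.048), the decoy receptor IL13RA2 (6.32 ± 0.11), GTSF1, a protein of the piRNA pathway (6.21 ± 0.055), HAPLN1 (6.03 ± 0.068), LOXL4 (5.83 ± 0.052) and the cytokine IL1A (5.72 ± 0.15). A2058 had higher levels of tyrosinase, TYR, the rate-limiting enzyme of melanin synthesis (-6.36 ± 0.11, A375 minus A2058), MMP1 (-6.16 ± 0.080), the retrotransposon-derived gene PEG10 (-5.55 ± 0.039), the surface protein CD200 (-5.26 ± 0.070), the fatty acid elongase ELOVL2 (-5.18 ± 0.056) and thrombospondin 2, THBS2 (-4.99 ± 0.057). In each of these 12 genes the limma adjusted p lay between 1.68e-16 and 9.03e-12. In all, 8541 genes differed, 4391 higher in A375 and 4150 higher in A2058, 1173 of them by at least 2-fold (615 and 558). Line and any batch that coincides with it cannot be told apart in this comparison.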

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

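The tests on immune cell and fibroblast markers, on the separation of the interferon genes between arrays, and both tests on the G1/S genes were chosen only after the result was seen; the lists of hypoxia and interferon ligand genes were written after the first fit. The hypoxia list was prompted by falls of 4 other hypoxia genes, which it leaves out, and some of its members stand in lists whose tests had been seen. That the ligand bound cannot exclude earlier transcription was noted only after its result was seen.

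The interferon genes rose in A375, by a median of 3.08, and their response differed from that in A2058 by a median of 2.99. Blood or immune cells in the A375 vemurafenib cultures are argued against by the immune markers, whose median change was 0.0279 over 14 genes, none of them called with a rise of 1 or more; the macrophage marker CD68, abundant in A375, rose by 0.92, and LYZ changed by -1.27. Fibroblasts are argued against by their 12 markers, with a median of 0.0313 and no call for COL1A1 (-0.023), COL1A2 (0.038) and COL3A1 (0.0044), abundant in such cells, although 5 markers rose, LUM by 2.15. A deviating array is argued against as well, since for 36 of the 38 genes all 3 vemurafenib arrays lay above all 3 DMSO arrays. Transcription of interferon by the A375 cells stays open: the largest rise among 16 ligand genes was 0.144, for IFNL2, and none was called, so no rise was seen at 72 h. That is the only time measured, and earlier transcription would be missed, so the bound of 0.5 set beforehand was wrong for excluding it. Of the 16 ligand genes, 15 also lay below the median gene in A375 vemurafenib, and changes of dim genes are understated. Probes of IFNA and IFNL genes can be shared between family members, and a response of the cells to the drug that does not pass through interferon transcription was not tested.

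G2/M genes rose (median 0.39, camera adjusted p = 2.04e-12, but adjusted p = 0.259 with an estimated correlation) and G1/S genes fell (median -0.42, adjusted p = 6.06e-08, but adjusted p = 0.246 with an estimated correlation) with vemurafenib in A375. A deviating array is argued against for both, since without A375 vemurafenib replicate 1 the medians were 0.482 and -0.31. Crowded, hypoxic A375 DMSO cultures may account for the G2/M part: hypoxia inducible genes fell by a median of -0.651, 22 of 25 called down and none up, and they lay higher in A375 DMSO than in A2058 DMSO by a median of 0.176. Single members lay on both sides in that comparison of the lines, such as NDRG1 (0.79) and PLOD2 (-0.52). Line and batch cannot be told apart in it. A direct effect of the drug on hypoxia genes would give the same fall, which was also seen in A2058 (median -0.256), so these explanations stay open side by side. As the cause of the G1/S fall crowding is argued against by the sign alone: slowed DMSO cells would make these genes rise with the drug, and their median was -0.423, with 29 of 40 called down and 3 up. Crowding next to another cause of that fall is not excluded.

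A375 vemurafenib replicate 1 deviated from replicates 2 and 3 by a median of 0.124 per gene in absolute size, against 0.0558 between replicates 2 and 3. An incomplete drug response in that culture cannot be told apart from other causes: the slope of its deviation on the drug effect was -0.077 (-0.071 with the effect and the deviation taken from separate arrays), between the bounds of -0.1 and -0.05 set beforehand. Array or RNA quality may contribute, since the deviation followed brightness, with a Spearman correlation of -0.348 across genes, and correlated at 0.498 with the deviation of A2058 DMSO replicate 2, an array of the other line. Beyond an incomplete response no biological explanation was tested, since the labels give none for a single array.

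For the difference of the responses, DMSO and vemurafenib were relabelled within the lines. Of 100 relabellings, 1, the real one, gave as many as 5434 genes, and the highest of the others gave 3736. Relabelling asks whether the drug had any effect, not whether the lines responded equally. Groups that mix treated and DMSO arrays also carry the drug effect in their spread, which lowers the number of calls. Whether chance made the responses differ therefore cannot be told from these counts. For the remaining contrasts the 10 splits of 6 arrays are too few for a share under 0.05: the real split gave 6816 genes in A375, 4991 in A2058 and 8541 between the DMSO groups, and the highest other split gave 0 in each case, with 1 of 10 splits as large as the real one.

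By the difference test 12 lists differed in response between the lines, 7 of them not with an estimated correlation. Medians (A375 minus A2058) were 2.99 for interferon, 1.18 for antigen presentation, 0.41 for G2/M, 0.28 for the undifferentiated state, 0.20 for ATF4 targets, 0.19 for ribosome biogenesis and 0.12 for fibroblast markers. Negative medians were -0.68 for pigment cell genes, -0.44 for cholesterol, -0.26 for AP-1, -0.23 for FOXO targets and -0.15 for glycolysis. With an estimated correlation adjusted p was 0.288 for G2/M, 0.242 for ATF4 targets, 0.288 for ribosome biogenesis, 0.231 for fibroblast markers, 0.376 for AP-1, 0.242 for FOXO targets and 0.0604 for glycolysis.

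Of 142 genes named in the text by the rule or its exceptions, the closing part included, 114 passed the limma difference test, and their log2 differences of response follow, A375 minus A2058. CD200, ELOVL2, PEG10 and THBS2 were also among the 6 genes highest in A2058 over A375 in DMSO. A375 may thus have had little room for a fall in these genes. The difference was 5.72 for IFIT1, 5.64 for TCN1, 5.22 for XAF1, 4.91 for OAS2, 4.90 for C1S, 4.47 for MMP1, 3.48 for OTULINL, 2.94 for CXCL8 and 2.88 for HLA-DMB. Next came 2.56 for LUM, 2.15 for IL24, 1.89 for CTSK, 1.89 for JUN, 1.73 for HLA-DMA, 1.65 for PSMB9, 1.43 for RGS5, 1.43 for TAP1 and 1.37 for VEGFA. It was 1.30 for CD200, 1.24 for PSMB8, 1.15 for ZEB2, 1.07 for PSMB10, 1.06 for GBP2, 1.02 for MRGPRX4, 1.0 for B2M, 0.99 for SESN3 and 0.93 for DUSP6. Further values were 0.92 for S100B, 0.91 for FOSL1, 0.89 for MRTO4, 0.88 for NLRC5, 0.85 for LYZ, 0.84 for ACTA2, 0.83 for ATF3, 0.77 for ELOVL2 and 0.73 for P2RX7. Then followed 0.73 for PEG10, 0.73 for THBS2, 0.71 for CD68, 0.70 for SOD2, 0.63 for SLC7A1, 0.61 for ETV5, 0.61 for GPNMB, 0.58 for KIF20A and 0.57 for DLGAP5. The smaller values were 0.55 for TFAP2A, 0.52 for SPRED1, 0.51 for CCND1, 0.48 for ERAP2, 0.48 for GINS3, 0.47 for TAPBP, 0.46 for ETV4, 0.45 for TXNIP and 0.43 for SLC7A11. Smaller again were 0.41 for MMP14, 0.40 for PDGFRB, 0.40 for PTGS2, 0.39 for NUPR1, 0.39 for KLF4, 0.39 for MKI67, 0.36 for SNAI2, 0.29 for PCNA and 0.29 for LOX. The last were 0.27 for FEN1, 0.27 for SLC2A1, 0.26 for DCN and 0.18 for NDRG1.

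Genes with a negative difference had a lower response in A375 than in A2058. LOXL4, HAPLN1, IL1A and IL13RA2 were also among the 6 genes highest in A375 over A2058 in DMSO, so A2058 may have had little room for a fall. The difference was -5.04 for SYTL5, -4.77 for LOXL4, -3.75 for FERMT1, -3.68 for HAPLN1, -3.58 for FBXO32, -3.55 for IL1A, -3.40 for TINAGL1, -2.99 for KCNJ13 and -2.97 for KIT. Next came -2.91 for VGF, -2.88 for TYRP1, -2.88 for TRIB2, -2.50 for ALDOC, -2.39 for EGR1, -1.83 for CRYAB, -1.81 for KLHL24, -1.67 for IL13RA2 and -1.60 for VLDLR. It was -1.40 for CEMIP, -1.37 for PDK1, -1.33 for SLC7A5, -1.21 for STARD4, -1.18 for BHLHE40, -1.12 for FN1, -0.91 for SPRY4, -0.75 for BNIP3 and -0.75 for P4HA2. Further values were -0.74 for WSB1, -0.71 for BNIP3L, -0.71 for MXI1, -0.70 for NOB1, -0.70 for LSS, -0.69 for NT5E, -0.64 for ITGA3, -0.63 for PFKM and -0.63 for CTH. Then followed -0.54 for FOXF2, -0.48 for TGFA, -0.47 for ACAT2, -0.46 for CDT1, -0.45 for TYR, -0.44 for EIF4EBP1, -0.44 for HMGCS1, -0.43 for EXO1 and -0.33 for DDIT4. The smaller values were -0.28 for FDPS and -0.27 for FBL.

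Probe sets without exactly 1 gene symbol were outside the comparisons. Of 13163 such probe sets, 1513 were called with vemurafenib in A375, 105 of them at 2-fold or more, and 924 in A2058, 43 of them at 2-fold or more.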

How the results depend on the processing

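Leaving out A375 vemurafenib replicate 1 and A2058 DMSO replicate 2 together was chosen only after seeing the data; the other settings were set beforehand. Of the comparisons with another setting, 3362 for named genes kept their direction and their side of the threshold, 45 lost it, 14 gained it and 17 changed sign; for list medians these numbers were 1426, 19, 20 and 44, and of the counts and the correlation 299 stayed within their bounds and 7 moved. Those 7 are as follows. With an estimated correlation 4 lists passed in A375 (8 with the preset one) and 5 in the difference (12 with the preset one), which counts the correlation within a list against it. Fry, which compares a list with no other genes, called 19 lists in A375 by its directional test, and by its mixed test 23 in A375, 24 in A2058 (14 by camera) and 24 in the difference. With both deviating arrays left out, the correlation of the responses was 0.347 (0.369 with all arrays); the cause was not tested.

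With each array left out in turn, the number of genes called ran from 6044 to 7785 in A375 (highest without A375 vemurafenib replicate 1), 4172 to 5952 in A2058, 4892 to 6638 for the difference and 7826 to 9361 between the DMSO groups. The number of lists ran from 8 to 9 in A375, 14 to 14 in A2058 and 11 to 14 for the difference, and the correlation from 0.361 to 0.371. Over the remaining settings the counts of genes lay at 6020 to 8127, 4415 to 6378, 4869 to 6953 and 7910 to 9849. With all probe sets, 8122, 5642, 5916 and 10753 of 32321 probe sets were called. With both deviating arrays left out the counts of genes were 7981, 5727, 6845 and 9053, and 5 members rose (3 with all arrays) in each of the falling G1/S list of A375 and ATF4 list of A2058. Leaving out the 30% of genes with the lowest mean kept these list calls and moved their medians in A2058 to -0.43 (undifferentiated state), -0.27 (cytokines) and -0.076 (receptor kinases), and to 0.20 for the fibroblast marker difference; the filter removes dim members. Shifting the arrays to the same median moved the share of rises from 47.9% to 43.6% in A375 and from 53.9% to 49.9% in A2058.

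Replicate numbers recur in all groups. The deviations of same-numbered DMSO and vemurafenib arrays correlated at -0.2, 0.1 and -0.13 in A375 and at 0.025, -0.027 and -0.2 in A2058, so the numbers were not taken as pairing, and not every array correlated best with its own number. With the replicate block, 6431 genes were called in A375, 4522 in A2058, 4934 for the difference and 8322 between the DMSO groups, with 8, 14 and 12 lists and a correlation of 0.369. Among named genes the block ended the call of FEN1 in A375 (adjusted p = 0.101) and changed no other call.

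Sign changes were seen for 7 genes and 16 list medians, none of them called in the main fit or in the setting that changed the sign; the cause was not tested. With the lowest 30% of genes left out the median was -0.010 for undifferentiated state in A375. With arrays shifted to the same median they were -0.0060 for BCL2 family, -0.011 for FOXO targets in A375; -0.0028 for interferon, -0.012 for immune, -0.013 for endothelial in A2058. With array weights they were -0.018 for BCL2 family, 0.028 for oxidative phosphorylation, -0.015 for matrix, -0.013 for fibroblast in A375; -0.0071 for endothelial, 0.00091 for TM7SF2 in A2058; -0.0085 for matrix in the difference. With both deviating arrays left out they were -0.018 for BCL2 family, 0.030 for oxidative phosphorylation, -0.018 for matrix, -0.019 for fibroblast, -0.00074 for immune in A375; -0.022 for STARD4, 0.038 for TM7SF2, -0.0098 for PSMB10 in A2058; -0.028 for matrix, -0.0067 for immune in the difference. With quantile normalization the values were 0.013 for oxidative phosphorylation in A375; -0.0031 for endothelial, 0.014 for MKI67, 0.0021 for ERBB3 in A2058. With each array left out in turn, the ranges with a sign change were -0.018 to 0.052 for BCL2 family, -0.020 to 0.030 for oxidative phosphorylation, -0.069 to 0.015 for ATF4 targets, -0.0079 to 0.031 for FOXO targets, -0.018 to 0.061 for matrix, -0.019 to 0.083 for fibroblast in A375. Others were -0.00074 to 0.043 for immune in A375. They were -0.0019 to 0.023 for interferon, -0.019 to 0.0080 for p53, -0.0027 to 0.025 for immune, -0.026 to 0.034 for endothelial, -0.059 to 0.023 for MKI67, -0.032 to 0.12 for VGF in A2058. Others were -0.037 to 0.056 for PMVK, -0.022 to 0.064 for STARD4, -0.051 to 0.038 for TM7SF2, -0.013 to 0.088 for PSMB10 in A2058. The last ranges were -0.060 to 0.0048 for receptor kinases, -0.0041 to 0.047 for immune, -0.052 to 0.0042 for endothelial in the difference.

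The genes whose calls changed with the setting were FEN1 and FOSL1 in A375, PFKM, ALDOC, ACAT2, NLRC5, TAP1, PSMB8, NFKBIZ, S100B, ST3GAL6 and EGFR in A2058, and TFAP2A and FBL for the difference. Over all settings, adjusted p ran from 0.00181 to 0.445 for the ribosome biogenesis list in A375 and from 0.0381 to 0.954 for the G2/M list in A2058. Signals near the lower end of the scale limit what can be seen for dim genes, and no measure of signal over background was used here.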

Other observations

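The list tests between the DMSO groups and all hypoxia tests were chosen only after the first results were seen. In DMSO, cytokines and chemokines were higher in A375: 22 of 27 were called higher, also adjusted over the list alone. The median was 1.63 (camera adjusted p = 1.89e-13, and adjusted p = 0.00063 with an estimated correlation). Pigment cell genes were higher in A2058 in 26 of 33 cases, also adjusted over the list alone. The median was -0.94 for A375 minus A2058 (adjusted p = 3.17e-11, and adjusted p = 0.00063 with an estimated correlation). All 45 G2/M genes were higher in A2058, also adjusted over the list alone, by a median of -0.84 (adjusted p = 1.53e-18, but adjusted p = 0.198 with an estimated correlation), as were 35 of 40 G1/S genes (36 adjusted over the list alone; median -0.65, adjusted p = 5.35e-13, but adjusted p = 0.157 with an estimated correlation). Ribosome biogenesis genes were higher in A375 in 25 of 41 cases, also adjusted over the list alone (median 0.27, adjusted p = 0.00117, but adjusted p = 0.333 with an estimated correlation). The other lists past the baseline test had these medians, A375 minus A2058, and none passed with an estimated correlation: 0.34 for AP-1 (adjusted p = 0.00239, and adjusted p = 0.333 with an estimated correlation), 0.12 for glycolysis (adjusted p = 0.0395, and adjusted p = 0.198 with an estimated correlation), 0.20 for p53 targets (adjusted p = 0.0147, and adjusted p = 0.198 with an estimated correlation), -0.23 for cholesterol (adjusted p = 0.0021, and adjusted p = 0.157 with an estimated correlation) and -0.17 for ATF4 targets (adjusted p = 0.00587, and adjusted p = 0.198 with an estimated correlation). Line and batch cannot be told apart in these values.

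Hypoxia inducible genes outside glycolysis fell in both lines. In A375, 22 of 25 measured genes were called down, among them NDRG1 (-1.79), BNIP3 (-1.78), BHLHE40, a circadian transcription repressor (-1.41), and P4HA2, a collagen prolyl hydroxylase (-1.01), while EGLN3 (0.056), LOX (0.0060) and SLC6A8 (0.020) were not called. In A2058, 15 were called down, among them NDRG1 (-1.97) and the angiogenic factor VEGFA (-1.94), and MXI1 (0.41), SLC6A8 (0.32) and WSB1 (0.27) rose. As a list the genes had a median of -0.651 in A375 and -0.256 in A2058, and the responses differed by a median of -0.304. BNIP3, BNIP3L, LOX and VEGFA also stand in other lists, and A375 vemurafenib replicate 1 stood apart from its group.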
